A study of Homo sapiens with 18 samples.

How the data were processed

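Gene-level RNA counts were analysed for 18 libraries of MDA-MB-436 cells, an established triple-negative human breast cancer line, in 8 groups. Per the labels, 6 were TruSeq stranded total RNA libraries, 3 of a control and 3 of SMARCAL1 knockout clone 1. The other 12 were PLATE-seq libraries, a pooled plate-based assay of polyadenylated RNA, with 2 each of a control, knockout clones 1, 2 and 3, an siRNA control and siRNA against SMARCAL1. The titles and count columns name MDA-MB-436 throughout, but the source names and cell line tags of the 12 PLATE-seq samples differ from sample to sample, from MDA-MB-437 to MDA-MB-448. These were assumed to be an error of filling in the labels, and all libraries were taken as MDA-MB-436. The replicates were those the labels call biological replicates. The deposited values were raw counts per gene symbol, made by the authors with STAR and HTSeq against hg38, per the submitters' processing notes, which gave no version, annotation release or strand setting. Without a stated strand setting, reads of a gene and of an antisense or overlapping neighbour could not be told apart.

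The TruSeq file held 57120 gene symbols. The PLATE-seq file held 44359 entries, of which 92 were spike-in controls. Spike-ins were left out of library sizes and tests, where they were 0.0534% or less of the counts of a library. In the TruSeq data 14 symbols, and in the PLATE-seq data 28, had been turned into dates by a spreadsheet. They were kept as written and not named. In the PLATE-seq data 4 entries shared a symbol with another and were kept apart. In the TruSeq data 14 symbols with at least 50 counts summed over the libraries had the same counts as another in every library. GENCODE release 29 held 57106 of the 57120 TruSeq symbols and 29226 of 44265 PLATE-seq symbols, and 29240 symbols were in both tables. Coordinates were taken from that release on GRCh38, 1-based, by symbol.

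Totals were 10257584 to 19270648 counts in the TruSeq libraries and 807872 to 3068902 in the PLATE-seq libraries. At these totals 3 counts, the floor used for a gene with no counts, were 0.165 to 0.278 CPM (counts scaled to library size) in TruSeq libraries and 0.911 to 3.72 CPM in PLATE-seq libraries. Floors and counting intervals cover counting error only, since amplified reads are not independent molecules. Replicate pairs differed by more than counting noise in each of the 8 groups, with chi-square per degree of freedom from 5.71 to 39.5.

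Each assay was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 17371 genes in TruSeq and 8595 in PLATE-seq. Library sizes were scaled by TMM, and the quasi-likelihood F test was run on a design with group as its only term. All 12 PLATE-seq libraries shared 1 fit, with 6 residual degrees of freedom. The TruSeq fit had 4. The biological coefficient of variation was 0.123 in TruSeq and 0.330 in PLATE-seq. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors were the fitted log2 fold change divided by the square root of F. Per-library levels are CPM with TMM library sizes, given as mean ± SD over libraries. "Rose" and "fell" are used for genes or lists past the threshold.

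The contrasts were clone 1 against control in TruSeq, and in PLATE-seq the equally weighted mean of the 3 clones against control, each clone against control, siRNA SMARCAL1 against siRNA control, the differences among the clones, the difference between the knockout and siRNA effects, and the siRNA control against the control of the clones. The labels do not say that a replicate number marks a shared batch or day, and the numbers were not taken to pair the libraries.

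Fixed gene lists, 23 in number, were tested with limma 3.58.1 camera at a preset correlation of 0.01, two-sided and adjusted over the lists of a contrast, and again with an estimated correlation. The core lists were interferon-stimulated genes, the cytosolic DNA and RNA sensing pathway, inflammatory cytokines and chemokines with interferons, MHC class I antigen presentation, immune checkpoint ligands and their regulators, the AP-1 family, and replication fork remodelling and protection. The context lists were NF-kappa-B targets, p53 targets, proliferation and mitosis, DNA replication, the unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol biosynthesis, NRF2 targets, and mesenchymal genes with extracellular matrix. The markers of cell state or of other cells were the luminal, basal, leukocyte and endothelial lists. The lists that track RNA composition were mitochondrially encoded messenger RNAs, cytosolic ribosomal proteins and replication-dependent histones. A list with fewer than 3 members tested was given no camera test, which held in PLATE-seq for leukocyte, endothelial and histone genes.

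Genes were named by a fixed rule. It took SMARCAL1 and CD274 in every contrast. In the TruSeq, knockout mean and siRNA contrasts it took the 8 largest rises and 8 largest falls among genes past the threshold with at least 5 CPM in the higher group and no overlap between the groups' libraries, leaving out clone-type names. It also took up to 3 members of each core list and up to 2 of any other list past the threshold by smallest p, and the 5 genes that differed most among clones by p. Genes past the threshold outside that rule, such as further list members, all calls of a contrast with few of them and the genes of clone 3, were named after their values were seen. Single libraries were left out in turn for the genes of the rule, the counts and the lists, not for those further members.

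The fit was tested on simulated counts drawn from the means and library sizes of the real libraries, with known changes. Of genes changed 2-fold, 73.5% were recovered in the TruSeq contrast (of 16724 genes tested), 7.27% in the mean of the clones (8168), 0.525% in clone 1 (8148) and 0.174% for the siRNA (8150). Of genes changed 4-fold, 92.9%, 65.4%, 49.0% and 48.5% were recovered, in the same order. False calls were 9.27% of calls in the TruSeq contrast at 2-fold and 6.97% at 4-fold. Effects of 2-fold were thus mostly below what a single PLATE-seq contrast could call.

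The alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 test, no filter, a filter at a mean of 5 CPM, the replicate number as a block, leaving out each library, fitting only the groups of a contrast, leaving out each clone, a test against a fold of 1.5, TruSeq counts thinned to a total of 1488653, and camera with an estimated correlation. The assays were compared by correlation across genes, where genes are not independent replicates, and by testing the TruSeq calls as lists in PLATE-seq. Overlap among clones, which share their control libraries, was set beside 20 simulations. These drew every group, the control included, from the same means. No column of the tables was left unused, and no library was left out.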

Results

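RNA was measured in 18 libraries whose titles name MDA-MB-436, an established triple-negative breast cancer cell line. SMARCAL1, an annealing helicase that remodels stalled replication forks, had been knocked out in clonal lines or depleted by siRNA. The series asks how SMARCAL1 bears on innate immune signalling and on PD-L1. TruSeq libraries of total RNA covered a control and knockout clone 1 with 3 biological replicates each, at 10257584 to 19270648 counts per library. PLATE-seq libraries covered a control, knockout clones 1, 2 and 3, an siRNA control and siRNA SMARCAL1 with 2 biological replicates each, at 807872 to 3068902 counts. The clone 3 libraries were the deepest of the PLATE-seq assay, with 2412226 and 3068902 counts, and the control libraries were among the shallowest, with 890878 and 807872. Replicates were those the labels call biological replicates.

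SMARCAL1 itself (chromosome 2, 216412414 to 216483053, plus strand, GRCh38) was not lower at the transcript level in the knockout libraries. In TruSeq it stood at 14.02 ± 0.696 CPM in clone 1 and 14.7 ± 1.21 CPM in the control (SD, n = 3 each; log2 fold change -0.07, SE 0.11, edgeR adjusted p = 0.791). Its raw counts were 163, 174 and 292 in control replicates 1, 2 and 3 and 144, 254 and 211 in those of the knockout. In PLATE-seq the control libraries held 0 and 3 counts, those of clone 1 held 3 and 6, of clone 2 held 8 and 3, and of clone 3 held 16 and 44. Relative to the library totals, clone 3 was at 6.20 times the control, with a 95% counting interval of 2.02 to 30.9 (exact binomial), clone 1 at 1.44 times (0.358 to 8.24) and clone 2 at 3.31 times (0.874 to 18.5). For clone 3 the edgeR adjusted p was 0.487. The labels do not state how the gene was disrupted, and a disrupted gene can keep its transcript level, so these values do not test the genotype. PLATE-seq tags polyadenylated ends, and a tag outside the disrupted part checks nothing. SMARCAL1 was lower in the siRNA libraries, the direction of their label, but at few counts. Both held 0 counts against 7 and 8 in the siRNA control, at least 4.84-fold lower with a floor of 3 counts over the group. The edgeR adjusted p over all genes was 0.573. Control replicate 1 of the clones also held 0 counts, so these counts do not establish the depletion.

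CD274, which encodes PD-L1 (chromosome 9, 5450503 to 5470566, plus strand), passed the threshold in none of the contrasts. In TruSeq it was at 2.48 ± 1.10 CPM in clone 1 and 3.88 ± 0.458 CPM in the control (n = 3 each; log2 fold change -0.67, SE 0.31, adjusted p = 0.261). Without knockout replicate 1 the change was -1.03 with an adjusted p of 0.0480, and over the omissions of single libraries it ranged from -1.03 to -0.43. In PLATE-seq the control was at 7.32 ± 6.85 CPM (n = 2), and clones 1, 2 and 3 were at 7.68, 10.8 and 13.6 CPM, with a mean change over the clones of 0.48 (SE 0.66, adjusted p = 0.860). The sign of that mean rests on control replicate 2, since the change was -0.21 without it. The siRNA libraries were at 19.3 ± 16.1 CPM against 25.1 ± 1.72 CPM in their control (-0.34, SE 0.66, adjusted p = 0.969), and the change was 0.29 without siRNA replicate 2.

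**Figure D1:**
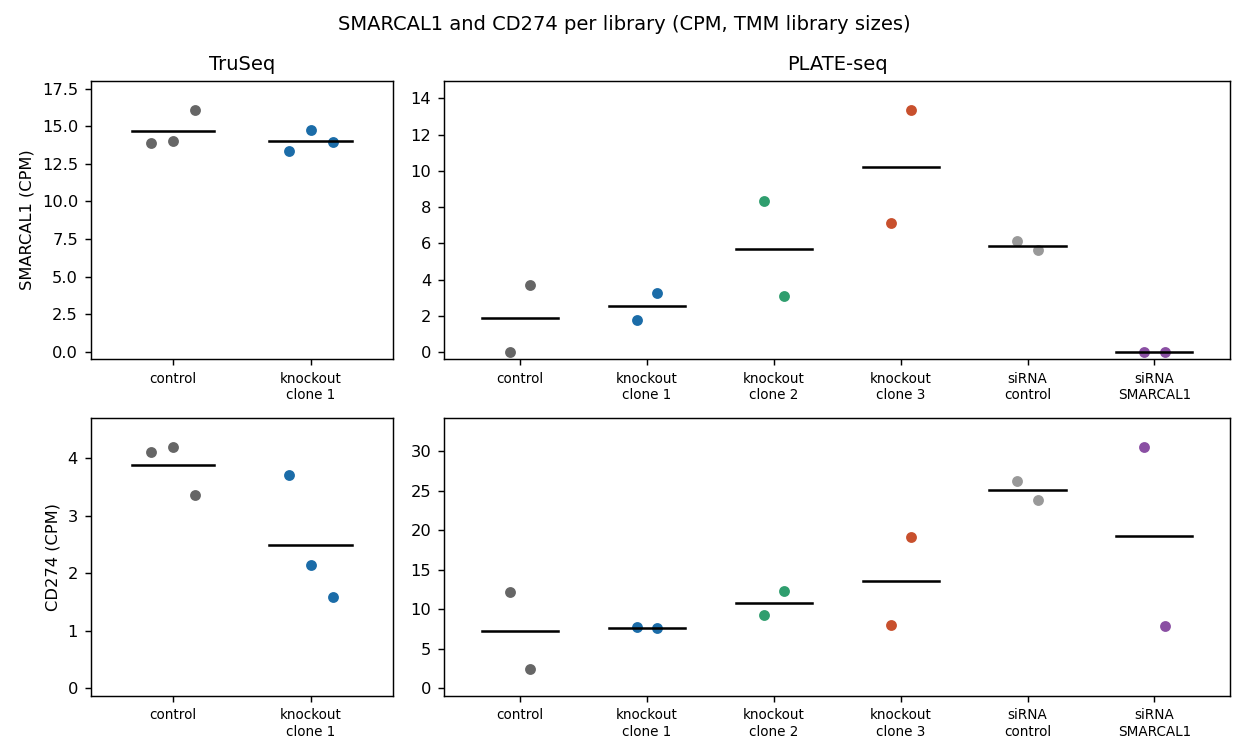
SMARCAL1 and CD274 in CPM per library (vertical axis) in TruSeq and PLATE-seq groups; each point is a library and each bar a group mean. SMARCAL1 counts are 0 in both siRNA SMARCAL1 libraries, while the TruSeq knockout mean of 14.02 CPM lies beside the control mean of 14.7 CPM.

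The TruSeq contrast asks what differs between knockout clone 1 and its control. Among genes past the threshold with at least 5 CPM in the higher group, the largest rise was that of SOX2, a stem cell transcription factor (chromosome 3, 181711924 to 181714436), from 0.457 ± 0.165 to 7.65 ± 1.33 CPM (n = 3 each; log2 4.07, SE 0.28, adjusted p = 0.000177). EHF, an epithelial ETS factor, rose by 2.96 (SE 0.21), the guidance ligand SEMA3A by 2.75 (SE 0.25) and the monocyte chemokine CCL2 (chromosome 17, 34255218 to 34257203) by 2.63 (SE 0.26), from 1.72 to 10.5 CPM. IGFBP5, a secreted binding protein of insulin-like growth factors (chromosome 2, 216672105 to 216695525), rose by 2.58 (SE 0.08) from 12.3 ± 0.591 to 73.3 ± 3.84 CPM, with an adjusted p of 5.20e-06. The sulfatase SULF2, the ligand WNT7B and the integrin ITGB8 rose by 2.42, 2.32 and 2.32. SULF2 overlaps exons of NCOA3 on the other strand.

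The largest falls among such genes were those of ENPP2, which encodes the lysophospholipase autotaxin (-4.64, SE 0.32; 28.6 ± 1.94 to 1.26 ± 1.00 CPM), and of the calcium channel subunit CACNB2 (-4.55, SE 0.28). Their order rested on 1 library, since ENPP2 was at -5.37 without knockout replicate 1 and at -4.32 without knockout replicate 2, and CACNB2 ranged from -4.68 to -4.37 over the omissions. SPARC, a secreted matrix protein (chromosome 5, 151661096 to 151687165), fell from 87.4 ± 4.32 to 4.86 ± 1.13 CPM (-4.16, SE 0.14, adjusted p = 5.20e-06). BST2, an interferon-stimulated restriction factor also called tetherin (chromosome 19, 17402939 to 17405648), fell from 20.2 ± 1.07 to 5.53 ± 0.775 CPM (-1.87, SE 0.13, adjusted p = 0.000177). The protease ADAM19 (-1.57), the integrin activator FERMT3 (-1.43), the growth factor FGF5 (-1.35) and BEX1 (-1.33) fell as well. FERMT3 lost its call without control replicate 2, with an adjusted p of 0.0558. ADAM19 overlaps CYFIP2 and FERMT3 overlaps TRPT1 on the other strand, and FGF5 overlaps CFAP299 on its own strand.

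**Figure D2:**
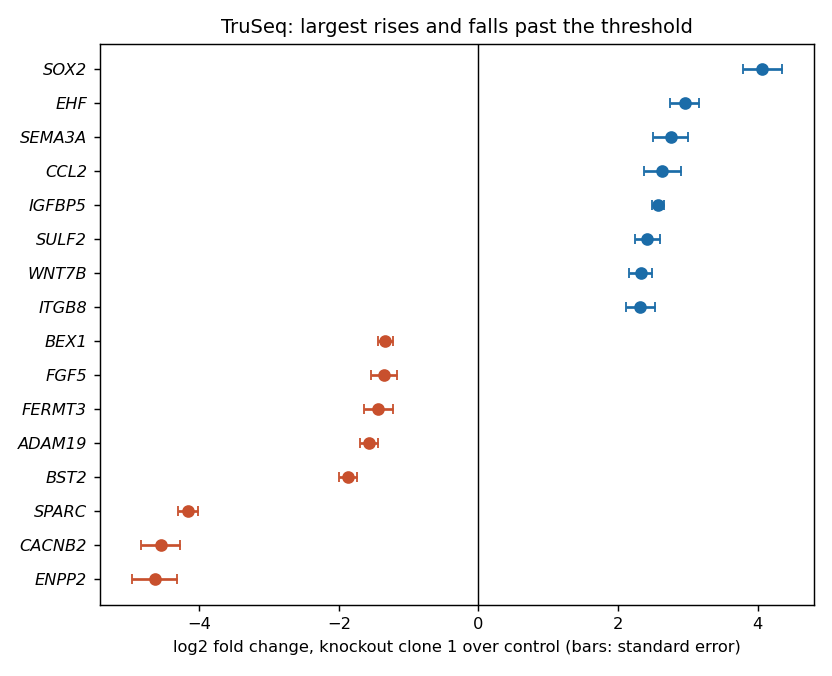
TruSeq log2 fold changes of knockout clone 1 against control (horizontal axis) for the 8 largest rises and 8 largest falls of genes with at least 5 CPM in the higher group; points are edgeR estimates and bars 1 SE, n = 3 libraries per group. SOX2 lies at 4.07 and ENPP2 at -4.64.

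Of 17371 genes tested, 1089 passed the threshold, 688 higher and 401 lower, and at an unadjusted p under 0.05 there were 3538. Groups did not overlap in any library for all 1089 genes and for 26.3% of all genes tested, where chance gives 10%. The count depended on the library left out. It was 518, 199 and 938 without control replicates 1, 2 and 3, in that order. Without knockout replicates 1, 2 and 3 it was 1145, 369 and 309. Libraries also split by the number of features detected, 36042 to 39068 in control replicates 1 and 2 and knockout replicate 1, and 28621 to 30653 in the other 3. Control and knockout lay apart on the second principal component of the TruSeq libraries (25.1% of the variance). The split by features lay on the first (50.03%), at -38.8 to -24.6 and 22.4 to 39.8. Its side with more features had lower totals, 10257584 to 12172405 against 15689281 to 19270648 counts. That side had a higher mitochondrial share, 0.637% to 0.891% against 0.302% to 0.370%. Fits within each side, which leave 1 library in an arm (1 of the knockout, then 1 of the control), called 1227 and 2517 genes.

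Inflammatory cytokines and chemokines rose as a group in clone 1: of 22 members tested, 10 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 2.86e-07, adjusted p = 0.247 with an estimated correlation). Beside CCL2, the alarmin IL1A rose from 115 ± 8.29 to 187 ± 15.4 CPM (0.70, SE 0.08), LIF from 109 to 168 CPM (0.62, SE 0.08) and CXCL8 from 104 to 177 CPM (0.77, SE 0.11). CXCL1 (0.84), IL15 (0.84), CCL20 (0.66), IL32 (0.49), IL6 (0.49) and IL1B (0.29) rose too, while IL11 fell (-0.97, SE 0.18). NF-kappa-B targets rose, with 7 of 25 members higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 5.39e-05, adjusted p = 0.152 with an estimated correlation). Members included the feedback inhibitors NFKBIA (0.51, SE 0.08), TNIP1 (0.47, SE 0.07) and TNFAIP3 (0.46), with TRAF1 lower (-0.69). NFKBIA and TNIP1 lost their calls without control replicate 2 or knockout replicate 3, at adjusted p from 0.0536 to 0.0600.

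The interferon-stimulated genes did not pass as a list: of 48 tested, 4 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.0777, adjusted p = 0.677 with an estimated correlation). SAMD9, an antiviral factor, rose by 1.36 (SE 0.15) from 10.7 to 27.4 CPM, OAS3 by 0.51, PARP14 by 0.43 and PSME1 by 0.28. BST2 fell, as did PNPT1, a mitochondrial RNA exonuclease (-0.64, SE 0.09). The list passed the threshold without control replicate 1 (0.0470), control replicate 2 (0.0467) or knockout replicate 2 (0.00730). In the cytosolic nucleic acid sensing pathway 3 of 24 members rose and 0 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0679, adjusted p = 0.247 with an estimated correlation). They were TRIM56, a ubiquitin ligase (0.62, SE 0.06; 69.7 to 107 CPM), TLR3, a sensor of double-stranded RNA (1.07, SE 0.17), and the kinase IKBKE (0.63, SE 0.10). TLR3 and IKBKE lost their calls without control replicate 2 (0.0536 and 0.0834), and IKBKE without knockout replicate 3 (0.0563). The sensing list passed without control replicate 3 (0.0441) or knockout replicate 1 (0.0331). With the replicate number as a block both lists passed by camera at the preset correlation (adjusted p = 0.0440 and 0.0398), although the numbers were not taken to pair the libraries.

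MHC class I antigen presentation genes rose slightly as a list (20 tested; adjusted p = 0.0165, adjusted p = 0.533 with an estimated correlation), with a median log2 change of 0.20. The list lost its call without knockout replicate 3 (0.0904). HLA-B alone passed, at 226 against 174 CPM (0.38, SE 0.09, adjusted p = 0.0492), and 5 rose adjusted over the list alone. HLA-B shares exons with HLA-C in the annotation, and its call was lost without control replicates 1 or 2 or knockout replicates 2 or 3 (0.1597 to 0.251). TAPBP (0.30, adjusted p = 0.0574) did not pass. Of 20 checkpoint ligands and regulators, the TNF family ligand CD70 rose (1.05, SE 0.15; 6.71 to 13.8 CPM), also adjusted over the list alone (list adjusted p = 0.386). NT5E (0.23, adjusted p = 0.0713) and ULBP2 (-0.37, adjusted p = 0.118) did not pass. Of 19 AP-1 family members 0 rose and 2 fell, also adjusted over the list alone, ATF4 (-0.39, SE 0.07) and FOSL2 (-0.30, SE 0.07). The median of that list was 0.05 while camera placed it lower (adjusted p = 0.565). FOSL1 was at -0.43 (adjusted p = 0.203), and at -0.26 without control replicate 1. ATF4 lost its call without control replicate 2 or knockout replicates 2 or 3 (0.0567 to 0.116) and FOSL2 on omission of any single library (0.0632 to 0.182). Of 39 fork remodelling genes, BOD1L1 rose (0.32, SE 0.07) and the recombination factor RAD52 fell (-0.48, SE 0.09), also adjusted over the list alone (list adjusted p = 0.386). PARP1 was at -0.26 (adjusted p = 0.0692). BOD1L1 lost its call without control replicates 2 or 3 or knockout replicates 2 or 3 (0.0600 to 0.153), and RAD52 without control replicates 1 or 2 or knockout replicates 2 or 3 (0.0521 to 0.106).

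Among the context lists, basal epithelial markers rose (6 of 16 higher, 0 lower, also adjusted over the list alone; adjusted p = 9.98e-06, adjusted p = 0.142 with an estimated correlation). KRT17, a basal keratin, rose from 12.99 to 44.6 CPM (1.78, SE 0.12), the alarmin S100A9 by 1.74 (SE 0.18) and the integrin ITGB4 by 1.03. Mesenchymal and extracellular matrix genes moved both ways, with 11 of 32 higher and 3 lower (14 and 3 adjusted over the list alone; adjusted p = 0.00220, adjusted p = 0.152 with an estimated correlation). TGFBI (1.503, SE 0.11), S100A4 (0.97) and THBS1 (0.86) rose, while SPARC, FN1 (-0.60) and CYR61 (-0.63) fell. Proliferation and mitosis genes fell slightly as a list, with a median of -0.13 over 30 genes (adjusted p = 0.00483, adjusted p = 0.152 with an estimated correlation). CDCA8 (-0.45, SE 0.06) and UBE2C (-0.27, SE 0.06) fell and KIF11 rose (0.26), with 7 lower and 1 higher adjusted over the list alone. CDCA8 lost its call without control replicate 2 (0.0560), and UBE2C on omission of any single library (0.0896 to 0.200).

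No other list passed. In p53 targets CDKN1A rose (0.97) and GADD45A fell (-0.56), of 28 tested (2 and 3 adjusted over the list alone; adjusted p = 0.982, with median and mean above 0 and the test lower). Hypoxia and glycolysis genes had NDRG1 higher and SLC2A3 and LOX lower, of 30 (2 and 3 adjusted over the list alone; 0.565). NRF2 targets had 3 of 22 higher, ME1, ABCC3 and UGDH (4 and 1 adjusted over the list alone; 0.423). DNA replication had MCM7 higher of 40 (0.872), and the stress response had ATF4 lower of 29 (0.763). Of 26 cholesterol biosynthesis genes 0 passed at an edgeR adjusted p (list 0.982, with a median of 0.04 and the test lower). Luminal markers had KRT7 higher of 12 (0.838), leukocyte markers 0 of 8 (0.259) and endothelial markers 0 of 8 (0.872). Among lists that track RNA composition, mitochondrial messenger RNAs had a median of -0.34 with 0 of 13 past the threshold (0.176). Ribosomal protein genes had 3 of 55 lower (2 adjusted over the list alone; 0.176), and replication-dependent histones 1 of 43 lower (0.101).

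In PLATE-seq the mean of the 3 clones was set against the control. This contrast averages the clones, with the spread taken between libraries and not between clones, so it does not show that each clone changed. DKK1, a secreted WNT antagonist (chromosome 10, 52314296 to 52318042), rose from 9.87 ± 1.68 CPM in the control (n = 2) to 100 ± 63.2 CPM in the knockout libraries (n = 6; log2 3.24, SE 0.61, adjusted p = 0.0176). PMEPA1, a target of TGF-beta signalling, rose by 1.80 (SE 0.34), the interleukin-7 receptor IL7R by 1.35 (SE 0.27; 107 to 276 CPM) and the proton pump subunit ATP6V0B by 1.24 (SE 0.23). The membrane protein CD109 fell by 3.32 (SE 0.58), the corepressor CTBP2 by 2.49 (SE 0.42; 51.0 to 11.3 CPM), ZCCHC7 by 2.07, the ubiquitin ligase NEDD4 by 1.76, the ribosome biogenesis factor NSA2 by 1.70 (SE 0.26), HMGN1 by 1.61 and the RNA-binding PABPC4 by 1.49 (SE 0.25; 223 to 81.6 CPM). Outside the naming rule, KNOP1 (-1.32), BEX1 (-1.36), CARS (-1.65), SRSF3 (-1.38) and AP000251.3 fell. GDPD1 fell as well; it held 8 and 47 counts in the control, 0 in clones 1 and 2 and 4 and 3 in clone 3, but also 0 in both siRNA control libraries. CTBP2 overlaps ZRANB1 on the other strand. BEX1 stood at 58.0, 37.2 and 135 CPM in clones 1, 2 and 3, against 170 CPM in the control. It also differed among the clones (edgeR F test adjusted p = 0.0113).

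These were all 17 genes past the threshold of 8595 tested, 4 higher and 13 lower, with 869 at an unadjusted p under 0.05. Without control replicate 1 the count was 7, without control replicate 2 it was 5 and without clone 3 replicate 1 it was 52, and each of the 17 genes lost its call without at least 1 of the 2 control libraries. Without control replicate 1 the change of CARS was -0.45 and that of SRSF3 -0.57, and without control replicate 2 that of CD109 was -1.82 and that of NSA2 -1.06. With the siRNA control in place of the control, a setting chosen after the data were seen, 20 genes passed, 8 higher and 12 lower. Of the 17, 1, IL7R (1.62, adjusted p = 0.00827), remained past the threshold and 11 kept their sign. ATP6V0B was then at -0.38. Of the 17, 5 also passed in TruSeq with the same sign: DKK1 (0.55), PMEPA1 (1.05), IL7R (0.56), BEX1 (-1.33) and PABPC4 (-0.46), where independent lists would share 0.221 higher and 0.384 lower genes. None of the others passed in TruSeq, where CD109 (0.25), NEDD4 (0.26) and ATP6V0B (-0.18) had the opposite sign and CTBP2 (-0.06), ZCCHC7 (0.02) and KNOP1 (0.03) were close to 0; AP000251.3 was not tested there.

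No list passed in the mean of the clones, with a lowest adjusted p of 0.629. The members of the core lists given here had an edgeR adjusted p of 0.231 or more. HLA-E was at 1.10 (SE 0.36), B2M at 0.49, OAS3 at 0.72 (SE 0.24), PSME1 at 0.69, IRF3 at 0.91, TRIM56 at 0.58 and MB21D1, the cGAS gene, at 0.96. Among cytokines IL24 was at -1.004, CSF3 at -0.54 and CXCL8 at 0.84. The AP-1 genes JUN, ATF4 and JDP2 were at -0.46, -0.38 and 1.30, the fork genes BOD1L1, CLSPN and HLTF at -0.53, -0.58 and -1.25, and the checkpoint genes ULBP2, RAET1G and PVR at -1.03, -1.21 and -0.36. Many of these rested on 1 library. Without control replicate 1 MB21D1 was at 0.46, ATF4 at -0.17, HLTF at -0.76, BOD1L1 at -0.31 and RAET1G above 0, without control replicate 2 JDP2 was at 0.38, IL24 at -0.24 and ULBP2 at -0.57, and without clone 3 replicate 2 B2M was at 0.26. In each of the 7 core lists 0 members passed adjusted over the list alone. Among the other lists, BIRC3, BCL3 and PLAU of the NF-kappa-B targets, PLK1 and BUB1B of the proliferation genes, ABCC3 and S100A4 were higher, and HMMR, ACAT2 and SPARC lower, adjusted over the list alone.

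Each clone was also set against the control. In clone 1 no gene passed by edgeR (704 at an unadjusted p under 0.05, 18 by DESeq2). Inflammatory cytokines passed as a list there (17 tested; adjusted p = 0.0292, adjusted p = 0.813 with an estimated correlation), and adjusted over the list alone CCL2 (3.01), CXCL8 (1.37), IL1A (1.14) and LIF (2.30) were higher and IL24 (-2.93) lower. In clone 2 the 3 genes past the threshold were DKK1 (3.91, SE 0.67), BEX1 (-2.19, SE 0.36) and CTBP2 (-4.01, SE 0.66). DKK1 and BEX1 lost these calls without clone 2 replicate 2, CTBP2 without clone 2 replicate 1, DKK1 without either control and BEX1 without control replicate 2. The clone 2 count was 13 without clone 3 replicate 1.

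Clone 3 had 57 genes past the threshold in the fit of all 12 PLATE-seq libraries, 26 higher and 31 lower. Fitted on the clone 3 and control libraries alone, 3 of the 57 passed and no others. SAA1 kept its call there (adjusted p = 0.00601), and IL1A (0.0576), TENM2 (0.0729), ATP6V0B, RPS28, KNOP1, NSA2 and PABPC4 did not. SAA1, an acute phase protein (chromosome 11), fell from 402 ± 87.2 to 50.2 ± 13.9 CPM (n = 2 each; -3.01, SE 0.31, adjusted p = 6.09e-06) and IL1A from 411 ± 103 to 99.4 ± 32.5 CPM (-2.04, SE 0.29, adjusted p = 0.00113). The colony-stimulating factor CSF3 fell by 1.35 (SE 0.28). TENM2 held 0 and 2 counts against 18 and 22 in the control, a ratio of 0.0155 relative to the totals with a 95% counting interval of 0.00181 to 0.0597. KNOP1 (-1.93), NSA2 (-2.07) and PABPC4 (-1.93) fell and ATP6V0B (1.70) rose. ATP6V0B lost its call without control replicate 1, PABPC4 without that library or clone 3 replicate 2, NSA2 without control replicate 2 and KNOP1 without clone 3 replicate 2 (adjusted p from 0.0758 to 0.126). Cytosolic ribosomal protein genes rose as a list (51 tested; adjusted p = 0.00117, adjusted p = 0.583 with an estimated correlation), with RPS28 at 3.83 (SE 0.65) and 7 higher and 1 lower adjusted over the list alone. RPS28 lost its call without clone 3 replicate 2 (1.65, adjusted p = 0.475) or control replicate 1. That clone 3 replicate had 10.7% of its counts in ribosomal protein genes and 24.6% in mitochondrial genes, against 9.38% and 32.7% in the other. The clone 3 count was 7 without control replicate 1, 27 without control replicate 2, 131 without clone 3 replicate 1 and 13 without clone 3 replicate 2.

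The clones differed from one another in 61 genes by an F test over the differences (974 at an unadjusted p under 0.05). IL1A (chromosome 2, 112773915 to 112784590) was at 903 CPM in clone 1, 373 in clone 2 and 99.4 in clone 3 (adjusted p = 2.52e-06). SAA1 was at 481, 372 and 50.2 CPM (2.52e-06), the neuropeptide precursor VGF at 28.8, 32.5 and 189 (0.000252), RPS28 at 22.4 in clone 1 and 388 ± 428 in clone 3 (0.000312; 85.8 and 690 in its 2 libraries) and the cytokine IL24 at 3.12, 12.4 and 45.2 (0.000536). Clone 3 was the clone farthest from the others in 50 of the 61 genes, higher in 28 and lower in 22. The count was 141 without clone 3 replicate 1, 17 without clone 3 replicate 2, 94 without siRNA control replicate 1 and 92 without control replicate 2.

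**Figure D3:**
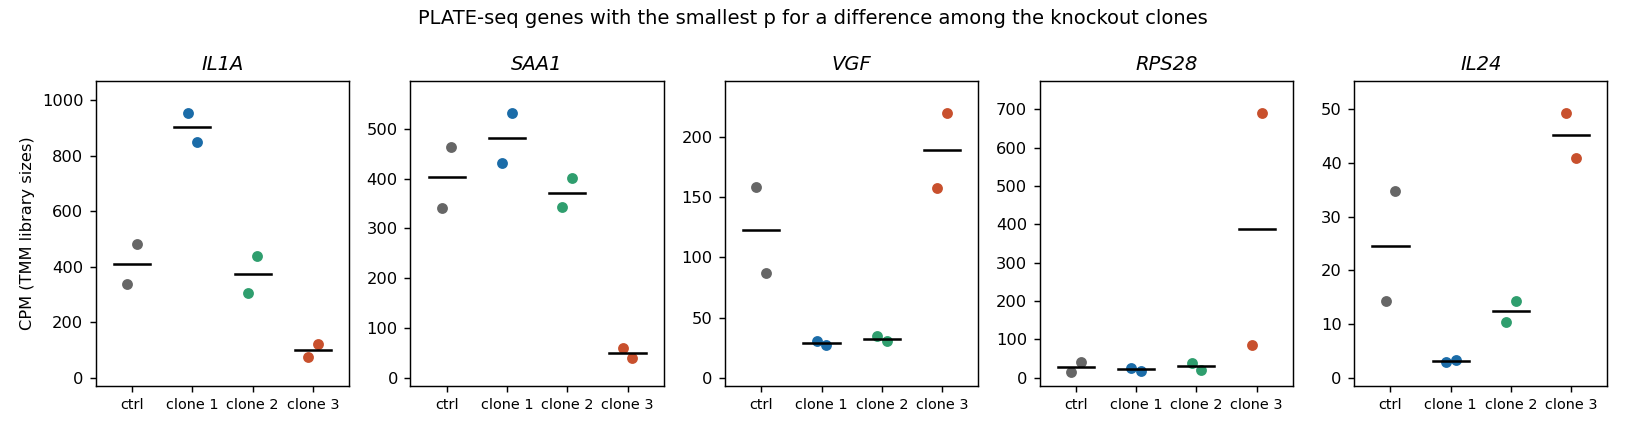
PLATE-seq CPM per library (vertical axis) of IL1A, SAA1, VGF, RPS28 and IL24 in the control and knockout clones 1, 2 and 3; each point is a library and each bar a group mean, n = 2 per group. IL1A falls from a mean of 903 CPM in clone 1 to 99.4 CPM in clone 3.

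Transient depletion by siRNA asks whether acute loss of the transcript gives the same changes. By edgeR 0 genes passed, with 544 at an unadjusted p under 0.05, 13 by DESeq2 and a lowest adjusted p of 0.166. No list passed (lowest adjusted p = 0.566). IL1A was at 1074 ± 174 CPM against 626 ± 126 in the siRNA control (n = 2 each; log2 0.78, SE 0.28, adjusted p = 0.590), CXCL8 at 69.9 against 29.4 CPM (1.25, adjusted p = 0.609) and CXCL3 at 85.0 against 42.0 CPM. Adjusted over the list alone, the chaperone CALR (1.36, SE 0.36, at 769 ± 580 CPM) passed among antigen presentation genes. So did the single-strand DNA binding protein RPA1 (2.76, SE 0.71, at 70.5 against 10.0 CPM) among fork genes. RPA1 stood at 46.6 CPM in the control of the clones and at 77.0, 81.6 and 24.4 CPM in clones 1, 2 and 3. The siRNA control was thus the lowest group for RPA1, and the change may rest on that low level. The CALR change rested on siRNA replicate 1, at 0.26 without it and at 1.98 (edgeR adjusted p = 0.00651 over all genes) without siRNA replicate 2. The other core members of the naming rule did not pass and went both ways: LGALS3BP (-0.95), ISG15 (-0.82) and PSME1 (0.40) of the interferon-stimulated genes, IFI16 (-1.33), TRIM56 (0.47) and TBK1 (-1.67) of the sensing pathway, PSMB9 (-1.95) and TAPBP (-0.52), CMTM4 (1.68), CD276 (1.46) and PVR (-0.67), ATF2 (-0.67), FOSL1 (-0.28) and JUND (0.45), and BRCA2 (-2.51) and FBXO5 (-2.43). Many rested on 1 library. Without siRNA control replicate 2 LGALS3BP was at -0.15, PSME1 at 0.19, TAPBP at -0.29, PVR at -0.40 and JUND at 0.05, and without siRNA control replicate 1 CD276 was at 0.83 and FBXO5 at -0.97. BRCA2 was at -1.51 without siRNA replicate 1, and TBK1 at -0.81 and ISG15 at -0.44 without siRNA replicate 2. RPA1 overlaps SMYD4 and PSMB9 overlaps PSMB8 on the other strand.

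The knockout and siRNA effects were compared by their difference, which passed in 0 genes by edgeR (667 at an unadjusted p under 0.05, 19 by DESeq2). Across genes the mean knockout and siRNA changes had a correlation of -0.03 with 51.4% of the same sign. The 2 kinds of control differed in 1 gene, ATP6V0B (1.62, SE 0.26, adjusted p = 0.0199; 758 CPM in the siRNA control and 247 in the control). That call was lost without control replicate 1 (1.45, adjusted p = 0.214) or siRNA control replicate 1 (1.28, adjusted p = 0.372). Inflammatory cytokines were higher in the siRNA control (17 tested; adjusted p = 3.55e-08, adjusted p = 0.103 with an estimated correlation), with CXCL2 (2.93) and CSF3 (1.32) past the threshold adjusted over the list alone. MHC class I genes and NF-kappa-B targets were also higher there (adjusted p = 0.0384 each, adjusted p = 0.243 and adjusted p = 0.254 with an estimated correlation). The labels do not say how the controls differ beyond the siRNA.

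Genes that had changed in TruSeq moved the same way in PLATE-seq clones 1 and 2 and not in clone 3 or under siRNA. Of the TruSeq calls, 713 were tested in PLATE-seq, 451 higher and 262 lower, and 553 (77.6%) had the same sign in clone 1, 531 (74.5%) in clone 2, 365 (51.2%) in clone 3 and 365 (51.2%) for the siRNA. WNT7B was at 2.90 CPM in the PLATE-seq control, 41.1 in clone 1, 31.5 in clone 2 and 1.43 in clone 3. Tested as lists by camera, the higher genes were up in clone 1 (adjusted p = 2.54e-13) and clone 2 (8.15e-13) and the lower genes down (5.76e-10 and 9.43e-06), each also past the threshold with an estimated correlation. The 4 tests in clone 3 and the siRNA contrast had adjusted p from 0.647 to 0.935. Between clones 3 and 1 the difference itself passed for the higher (2.54e-13) and lower genes (5.80e-08). Across the 8177 genes tested in both assays, the TruSeq change correlated with that of clone 1 at a Pearson r of 0.28 (Spearman 0.27), of clone 2 at 0.24, of clone 3 at 0.04 and of the siRNA at 0.02. Over the 713 calls alone, the correlation with clone 1 was 0.55 (Spearman 0.59). The assays share no library.

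**Figure D4:**
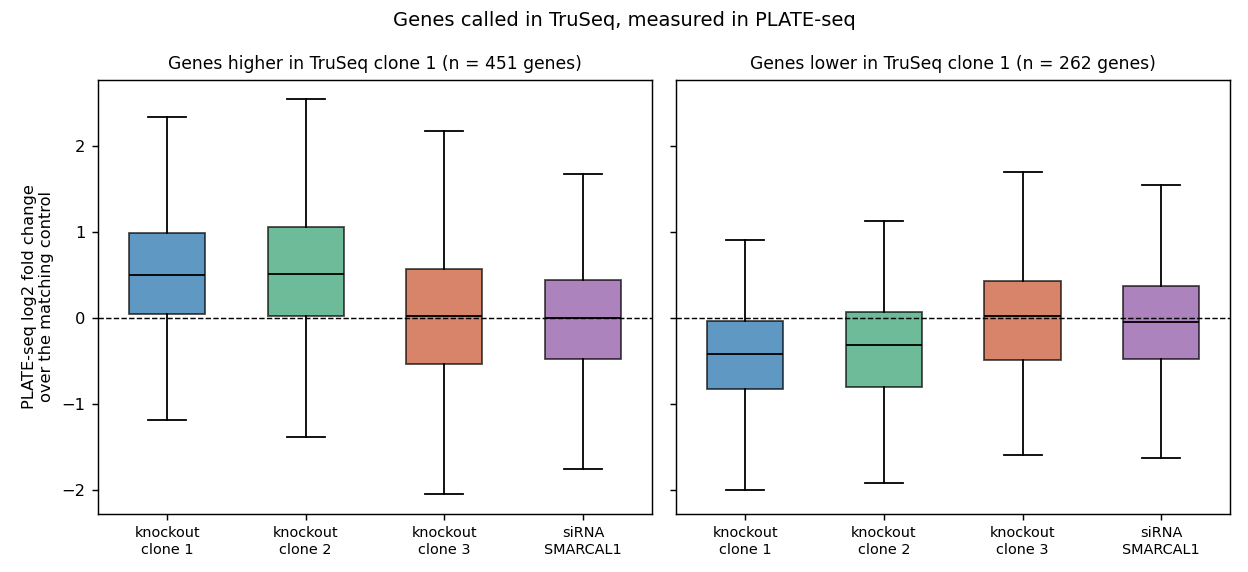
PLATE-seq log2 fold changes (vertical axis) in clones 1, 2 and 3 and the siRNA contrast of the 451 genes higher and 262 lower in TruSeq; boxes are quartiles with the median, and outliers are not drawn. Medians of the higher genes are 0.50 in clone 1, 0.51 in clone 2, 0.03 in clone 3 and 0.00 for the siRNA.

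The 3 clones share their 2 control libraries, which alone gives their changes a correlation. Observed correlations were 0.67 for clones 1 and 2, 0.65 for 1 and 3 and 0.56 for 2 and 3, against 0.54, 0.58 and 0.55 in 20 simulations without any effect. The covariances were 0.720, 0.648 and 0.626 against 0.288, 0.291 and 0.290 simulated, a difference of 0.431, 0.357 and 0.337. Signs matched in 72.4%, 68.1% and 66.0% of genes against 67.6%, 68.5% and 67.9%. Calls of clones 2 and 3 shared DKK1 (1 gene, against 0 on average in the simulations and 0.00303 for independent lists), and clone 1 had no edgeR call to share. For clones 2 and 3 the correlation of 0.565 lay below the highest simulated one, 0.569. The simulated control had the same means as the clones, so any offset of the real control libraries was left out. The 2 control libraries were not split, which would leave 1 library to each clone of a pair, so part or all of the excess may come from the shared controls.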

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

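The contrasts, gene lists, naming rule and the other alternatives were fixed before the data were examined; the tests of the TruSeq calls in the PLATE-seq clones and siRNA contrast, the exchange of controls, the thinning of clone 3 and the split by features detected were chosen only afterwards.

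The 3 clones differed from one another in 61 genes by edgeR's F test, and IL1A (adjusted p = 2.52e-06), SAA1 (2.52e-06), VGF (0.000252), RPS28 (0.000312) and IL24 (0.000536) differed most. IL1A stood at 903, 373 and 99.4 CPM in clones 1, 2 and 3, and RPS28 in clone 3 rested on 1 library, at 85.8 and 690 CPM in replicates 1 and 2. The genes that had risen or fallen in TruSeq clone 1 differed as groups between PLATE-seq clones 3 and 1 (camera adjusted p = 2.54e-13 and 5.80e-08, median differences of -0.48 and 0.42) and between clones 3 and 2 (2.45e-12 and 0.000218). They also differed between the mean knockout effect and the siRNA effect (0.000823 and 0.00371, medians of 0.32 and -0.24). Spike-in controls, which no comparison used, held 351 to 632 counts in every PLATE-seq replicate 1 library and 3 to 17 in every replicate 2 library.

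The first pattern weighed was the 1089 genes past the threshold between TruSeq clone 1 and control. Of the 10 splits of the 6 libraries into 3 and 3, 2 called at least as many genes, the real one and the split by features detected (1545), and 10 splits are too few for a share under 0.05. That second split points to a structure of the libraries. It lay on their first principal component (50.03% of the variance), and control and knockout lay apart on the second (25.1%). Totals and mitochondrial share differed along with the split, and its cause was not tested. With the split by features as a term in the fit 100% of the 1089 genes stayed past the threshold. All 1089 had been called with no overlap between control and knockout libraries, across that split, so this outcome was close to fixed in advance. It does not decide on the split as a cause, and neither do fits within its sides, each with 1 library in an arm. The median change of these genes in the TruSeq direction was 0.47 in PLATE-seq clone 1 and 0.42 in clone 2 (95% bootstrap interval 0.37 to 0.48). The bootstrap here and below resampled genes, so its intervals do not measure the spread between libraries. As lists these genes also passed in clone 2 by camera with an estimated correlation (adjusted p = 7.76e-05 for the higher and 0.000320 for the lower). Together these values argue against a change of clone 1 alone. The median was 0.0121 under siRNA (-0.0444 to 0.0591) and 0.01 in clone 3. A candidate explanation is a state of clones 1 and 2 that does not follow from loss of SMARCAL1. Incomplete loss in clone 3 stays open as well, but SMARCAL1 counts do not test the genotype. Clone 3 held the most (16 and 44) in the deepest libraries, at 7.11 and 13.4 CPM, against 8.32 and 3.07 CPM in clone 2. For the siRNA, a slow response that transient depletion does not give and a different baseline in the siRNA control stay open. None of these was tested, and the counts do not favour 1 of them.

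The second pattern was the 57 genes past the threshold in clone 3 beside 0 in clone 1 by edgeR (704 at an unadjusted p under 0.05 and 18 by DESeq2). Clone 3 libraries were the deepest, but thinned to the totals of clone 1 they still called a median of 52 genes (49 to 56 in 5 draws), which argues against depth as the cause. Fitted on the clone 3 and control libraries alone, 3 of the 57 genes passed, IL1A and TENM2 not among them, and so the calls rest on the spread taken from all 12 libraries. A difference between the clones themselves, as a group of the design, may underlie the pattern. Residual SMARCAL1 could not be tested from its counts, which were highest in the deep clone 3 libraries (16 and 44). The clone 3 count was 131 without its replicate 1, 13 without its replicate 2, 7 without control replicate 1 and 27 without control replicate 2, so single libraries stay open as a source.

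The third pattern was the 17 genes past the threshold in the mean of the clones. Their median change in the called direction was 1.70 against the control and 0.51 against the siRNA control (95% interval of a bootstrap over genes -0.04 to 1.05). This is consistent with control libraries that stand apart from the rest, although genes picked for their distance from a control would likely move back against any other. On the second principal component of the PLATE-seq libraries (13.3% of the variance) the control libraries lay at 31.1 and 61.4. The other 10 libraries lay at -20.8 to 1.99. On the first (14.1%) the clone 2 libraries lay apart, at -39.5 and -45.8, with all others at -12.6 to 27.2. The control and clone 2 libraries had the lowest totals, 807872 to 960434 counts. Depth may thus bear on both components, which was not tested. The siRNA control had itself been given an siRNA. Its cytokine list was higher than in the control by camera at the preset correlation, but did not pass with an estimated one. Against it 20 genes passed, 1 of them among the 17. The exchange thus gave another list and not fewer calls, and does not say which control is the better baseline.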

How the results depend on the processing

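The settings that use the split by features detected, subsets of libraries by that number, the siRNA control in place of the control and the TruSeq calls as lists were chosen after the data were seen; the rest were planned. Of 309 values for the contrasts, lists and targets under alternatives, 226 kept their direction and side of the threshold or, for counts, stayed within 1.5 times, 4 were weaker, 26 stronger, 6 reversed and 47 moved. Of 2329 values for named genes and lists, 2101 were the same, 162 weaker, 43 stronger and 23 reversed. Except where the construction shows it (fewer libraries, fewer counts or other genes tested), the cause was not tested. Depth limits the calls: thinned to the mean PLATE-seq total, the TruSeq contrast called 314 genes in place of 1089, of which 288 were among the 1089.

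The TruSeq count was 70 against a fold of 1.5, 3793 with the split by features as a term, 2517 in the 3 libraries with the fewest features (1 control, 2 knockout) and 199 to 1145 on leaving out single libraries. With the replicate number as a replicate block it was 2387, including all 1089 genes, and 10 lists passed in place of 6, interferon-stimulated genes (adjusted p = 0.0440) and the sensing pathway (0.0398) among those gained. Deviations of 2 of 3 same-numbered TruSeq pairs correlated above 0.1 (-0.27 to 0.58 over the 3), and those of 0 of 30 PLATE-seq pairs did, so the numbers were not taken to pair the libraries, although spike-in counts split by number in PLATE-seq. With the block the contrast of the knockout and siRNA effects called 2 genes in place of 0, and no other PLATE-seq count moved by more than 1.5 times. Of the 17 genes of the mean of the clones, NEDD4 (-1.77, adjusted p = 0.0570), HMGN1 (-1.61, 0.0644) and AP000251.3 (-3.74, 0.0570) did not pass with the block. Of the 6 TruSeq lists past the threshold, 0 passed with an estimated correlation and 6 to 9 lists passed on leaving out single libraries. SMARCAL1 in TruSeq was at 0.0816 after thinning and at -0.108 to 0.0110 without single libraries, and CD274 at -1.03 to -0.43.

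By DESeq2 the counts were 53 for the mean of the clones, 18, 39 and 122 for clones 1, 2 and 3, 13 for the siRNA, 163 for the differences among clones, 19 for the knockout against the siRNA effect and 5 for the controls. Without a filter they were 83, 36, 61, 156, 22, 230, 44 and 35, in the same order. Fitted on only the groups of the contrast, clone 2 called 1 gene, clone 3 called 3, the siRNA 1, the differences among clones 39 and the controls 0. Of the named genes, 7 of 8 in clone 3, BEX1 and CTBP2 in clone 2, and HMGN1 and AP000251.3 in the mean did not pass there, where fewer libraries give the spread. The mean of the clones called 11 genes with clone 2 left out, and 0 genes passed the same way in each of the 3 clones, which the 0 calls of clone 1 fix in advance. Leaving out single libraries gave 5 to 52 genes for the mean, 0 to 7, 3 to 13 and 7 to 131 for clones 1, 2 and 3, 0 to 2 for the siRNA, 17 to 141 for the differences among clones, 0 to 15 for the knockout against the siRNA effect and 0 to 4 for the controls. The lone library left in a group was then assumed to vary like the other groups. The correlation of clone 1 between the assays was 0.55 over the TruSeq calls, against 0.28 over all genes tested in both.

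With the siRNA control in place of the control, the mean of the clones reversed for ATP6V0B (-0.38), GDPD1 (1.35), CD109 (0.78), HMGN1 (0.0414), TRIM56 (-0.0622), CXCL8 (-0.0612), HLA-E (-0.17), RAET1G (0.76), CLSPN (0.41), KNOP1 (0.0325), SRSF3 (0.19), SMARCAL1 (-0.14) and CD274 (-1.25). Without single libraries the mean of the clones ranged from -2.18 to 5.97 for RAET1G and from -0.21 to 2.05 for CD274, and the siRNA change of CD274 from -1.65 to 0.29. List directions that reversed without single libraries never passed: adjusted p in the mean of the clones was 0.682 to 0.991 for interferon-stimulated genes, 0.687 to 0.991 for cytokines, 0.846 to 0.991 for checkpoint genes, 0.793 to 0.991 for AP-1 and 0.749 to 0.991 for fork genes, and for AP-1 under siRNA 0.621 to 0.975.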

Other observations

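The genes and regions described here were chosen only after their values were seen. Around SMARCAL1 on chromosome 2, 9 other genes within 1 Mb were tested in TruSeq and 3 of them passed the threshold. IGFBP5 (216672105 to 216695525) rose by 2.58 (SE 0.08), and its neighbour IGFBP2, another binding protein of insulin-like growth factors (216632828 to 216664436), rose by 0.70 (SE 0.14, adjusted p = 0.0255). They lie 0.189 and 0.150 Mb beyond the end of SMARCAL1. FN1, the matrix protein fibronectin (215360440 to 215436172), 0.976 Mb before its start, fell by 0.60 (SE 0.06, adjusted p = 0.00137). The nearest tested gene, RPL37A, was at 0.09 (SE 0.15) and the DNA repair gene XRCC5 at -0.03 (SE 0.06), neither past the threshold. Of 17322 windows of the same size around other tested genes, 15.04% held at least 3 genes past the threshold and 3.46% held as high a share of them.

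Among the 57 genes past the threshold in PLATE-seq clone 3, 11 had also passed in TruSeq clone 1, 6 with the same sign and 5 with the opposite one. Those with the opposite sign were the vasoconstrictor peptide EDN1 (-3.80 in clone 3 and 1.39 in TruSeq), the tight junction protein CLDN1 (-3.04 and 1.24), IL1A (-2.04 and 0.70), DNER (-2.04 and 0.54) and the centromere factor MIS18A (1.70 and -0.50). In PLATE-seq EDN1 was at 1.46 in clone 1 and 1.21 in clone 2, neither past the threshold. Genes with the same sign were DKK1, PMEPA1, PABPC4, S100A10 (1.41 and 1.24), NDUFA4 (1.60 and 0.53) and LPAR3. Independent lists would share 1.32 higher and 0.961 lower genes, and the lists shared 4 and 2. No such value was computed for the 5 genes of opposite sign, so these counts do not show an agreement in direction.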
